A study of Mus musculus with 4 samples.

How the data were processed

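Total RNA of 4 cultures of bone marrow-derived mast cells, 2 wild-type and 2 Pac1-/-, had been hybridised to Affymetrix mouse 430A arrays, 1 array per culture. Per the labels' protocols, 500 to 1000 ng of RNA was amplified by a method for small samples and labelled as biotinylated cRNA, and over 98% of cells stained for Kit and FceRI before the stimulation. Per the series' design text, the cultures were independent, and the p-values use the spread between the 2 cultures of a genotype. Most of that spread was a difference between the replicate numbers that both genotypes shared. Of the sum of squares, 71.9% lay between the numbers, against 10.2% in the remainder. The p-values therefore do not measure independent variation between cultures alone.

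The authors deposited 1 table of linear intensity values per probe set, made with MAS5 per the submitters' processing notes. The trimmed mean of each array in the table, leaving out 2% at either end, was between 150.06 and 150.08, so the arrays had been scaled to a common mean. The series' design text describes another route, in which the arrays were normalised by RMA, tested with eBayes of Limma version 1.3.12 with adjusted p-values, and filtered on a mean intensity of 100; RMA values were not used here. The text leaves open whether its threshold of 0.05 was on adjusted p-values, and both counts are therefore given.

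The table holds 22690 probe sets, of which 64 controls were left out. By the platform annotation, 20380 of the others have 1 gene symbol, 691 have several and 1555 have none; only probe sets with 1 symbol are named. The rule written for a linear table was used. The 4 arrays were quantile normalised on the linear scale, values below 16 were set to 16, and log2 was taken. The size of a log2 difference depends on this floor where an array reads at or near it. Where a gene reads below 100 on any array, a size given for it is approximate. Probe sets with a mean intensity of at least 100 over the 4 arrays were tested, 7770 in all, and 14856 below it were left out of the tests. Differences were fitted with limma 3.58.1 (lmFit and eBayes, genotype as the only term, two-sided, Benjamini-Hochberg threshold 0.05) in R 4.3.3. Each test has 2 residual and 1.7 prior degrees of freedom. An exact permutation test of 2 against 2 arrays cannot give a p below 0.3333, so none is reported. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

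For gene lists each gene was represented by its brightest probe set, which gave 4998 genes. The 23 lists hold 746 entries for 731 genes, of which 325 were tested. The lists are mast cell granule, protease and receptor genes; cytokines and chemokines; immediate-early transcription factors; feedback regulators of MAP kinase signalling; MAP kinase cascade components; NF-kappaB genes; calcium and NFAT signalling; proximal FceRI signalling; prostaglandin and leukotriene synthesis; interferon response; cell cycle; apoptosis and survival; heat shock and unfolded protein response; cholesterol synthesis; glycolysis; ribosomal proteins; markers of macrophages, neutrophils, basophils and eosinophils, lymphocytes, erythroid cells and megakaryocytes, and stromal cells; and sex-linked genes. Lists with at least 5 tested genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists.

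The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Dusp2. It then takes, per direction, the 12 genes with the largest difference among those past the adjusted test whose genotypes do not overlap, filled up from genes past the unadjusted test with the same property. It last takes up to 4 tested members per list with the lowest p. No gene passed the adjusted test, so all 24 places were filled at the unadjusted level. Cpa3, Cma1, Fcer1a, Srgn, Ms4a2, Mcpt2, Egr1, Il6, Ccl3 and Tnf are outside the rule and were chosen after their values were seen.

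The alternatives were the values as deposited, centring on each array's median, no intensity minimum, a minimum of 200, the minimum applied after the adjustment (the order in the series' design text), a floor of 64, an intensity trend in eBayes, the replicate number as a block, leaving out each array in turn, averaging the probe sets of a gene, camera with an estimated correlation, and fry. With an array left out, the lone array of its genotype is assumed to vary like the other genotype. It is also set against both replicate numbers of that genotype, so part of the difference between the replicate numbers enters the genotype difference.

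The steps were tested on simulated data made from the 7770 tested probe sets with 1 spread for all, pooled from that measured between replicates. At that spread, 0 of 100 probe sets changed by 1 log2 unit and 3 of 100 changed by 3 log2 units were recovered, with 0 false calls. At 0.1 of the spread 100 of 100 of either size were recovered, with 17 false calls. Camera called a simulated list of 40 members shifted by 1 log2 unit, and did not call one left unshifted. The simulated noise was independent between probe sets and arrays and held no difference between replicate numbers. It therefore does not show how often camera would call an unshifted list in these data. Neighbouring genes of Dusp2 were taken from the RefSeq annotation of assembly GRCm38.p6, used for gene order only.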

Results

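Gene expression was measured in mouse bone marrow-derived mast cells, which were grown from marrow of 8 to 12 week-old mice for 4 to 6 weeks with 5 ng/ml interleukin-3. The cells were either wild-type (Pac1+/+) or lacked Pac1 (Pac1-/-), the dual-specificity MAP kinase phosphatase encoded by Dusp2. All cultures were loaded with IgE against dinitrophenyl for 18 h and then activated through the high-affinity IgE receptor FceRI with 20 ng/ml of the antigen DNP-HSA for 2 h. Each genotype was represented by 2 cultures, numbered replicates 1 and 2, and each culture by 1 array, so the number of arrays limits the precision of every value. No unstimulated culture is among the 4 arrays, and the comparison therefore concerns activated cells only. Between 27.8% and 33.9% of probe sets per array had a deposited intensity of at least 100. The lowest share was on Pac1-/- replicate 2, where the median intensity was 24.5, against 49.3 and 47.9 on the wild-type arrays and 40.5 on Pac1-/- replicate 1.

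Several mast cell transcripts, chosen after their values were seen, were bright on all 4 arrays. In wild-type and Pac1-/- cells respectively, the normalised intensity of the granule carboxypeptidase Cpa3 lay between 8968 and 12388 and between 8770 and 12388, and that of the chymase Cma1 was 10267 on both wild-type arrays and 10464 and 11000 on the Pac1-/- arrays. The FceRI alpha chain gene Fcer1a lay between 6915 and 10064 and the proteoglycan core gene Srgn between 4913 and 8420 over the 4 arrays. Others were not: the FceRI beta chain gene Ms4a2 read 142.6 and 41.9 on the replicate 1 arrays and 3261.1 and 1502.3 on the replicate 2 arrays, and the protease gene Mcpt2 read 28.4 and 15.7, then 216.4 and 197.9, for wild-type and Pac1-/- in turn. The immediate-early transcription factor gene Egr1 was also present on every array, at 1072 and 1012 in wild-type cells and at 970 and 1737 in Pac1-/- cells.

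The first question was whether the Dusp2 signal differed between the genotypes. The array has 1 Dusp2 probe set, which had deposited intensities of 173.7 and 99.4 in wild-type replicates 1 and 2 and of 116.9 and 51.6 in Pac1-/- replicates 1 and 2. After normalisation these were 167.2, 90.7, 109.3 and 75.5. The log2 difference, Pac1-/- minus wild-type, was -0.44 ± 0.51 (SE, n = 2 per genotype; 95% confidence interval -1.90 to 1.02; limma adjusted p = 0.888), and it was -0.61 between the replicate 1 arrays and -0.26 between the replicate 2 arrays. The genotypes overlapped, and without wild-type replicate 1 the difference was 0.003. The position of the probes relative to the deleted part of the gene is not given in the sources used here, so this signal does not check the genotype labels.

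The second question was which transcripts of activated mast cells depended on Pac1. Among genes with lower signal in Pac1-/- cells were the transcription factor genes Ikzf1 (Ikaros) and Runx1, the cytokine signalling inhibitor Socs1, glutathione reductase Gsr and the stress-induced pseudokinase gene Trib3. Among genes with higher signal were the chromatin organiser Satb1, the lysozyme gene Lyz1, the T-box factor Eomes and carboxypeptidase Cpe. None of these genes passed limma's test after Benjamini-Hochberg adjustment: of 7770 probe sets tested, 0 had an adjusted p under 0.05 and the lowest adjusted p was 0.866. At an unadjusted p under 0.05 there were 263 probe sets, 175 higher and 88 lower in Pac1-/- cells, where chance alone would give 388.5. This fit had genotype as its only term, so differences between the replicate numbers entered its error, and a count below chance does not show that the genotypes were alike. With the replicate number as a block, a pairing that the labels do not give, there were 899, 328 higher and 571 lower. The higher share was 66.5%, against 54.2% on the values as deposited, 92.7% when each array was centred on its median and 36.5% with the replicate block. No direction therefore held over these settings. Shares with an array left out are not compared here, because part of the replicate difference enters the genotype difference in those fits. In 2932 probe sets, 37.7%, both Pac1-/- arrays lay on the same side of both wild-type arrays, against 33.3% by chance.

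The genes named here passed the unadjusted test only, had groups that did not overlap, and had a limma adjusted p of 0.866 each. All but Trib3 and Cdc37 read below 100 on at least 1 array, so the sizes given are approximate. Ikzf1 had a log2 difference of -3.80 ± 0.96 (SE, n = 2 per genotype), with -4.22 between the replicate 1 arrays and -3.38 between the replicate 2 arrays. Gsr was at -3.26 and Socs1 at -3.01. For Ikzf1, Gsr and Socs1 the Pac1-/- replicate 2 array was at the floor of 16, so the size and rank of their differences depend on that floor. Runx1 had a log2 difference of -2.44 ± 0.83 and Trib3 of -2.16 ± 0.41. Each had 2 tested probe sets of the same sign, but so had 50.8% of 1468 genes by their 2 brightest, about as many as by chance, and the genotype difference correlated between these at r = 0.1014 (-0.0714 in 451 genes where neither probe set is of a type that may bind several transcripts). The other genes with lower signal were the mitochondrial carrier gene Slc25a42 (-2.71), the ribosome maturation factor Sbds (-2.27), the ubiquitin-conjugating enzyme Ube2c (-2.06), the Hsp90 co-chaperone Cdc37 (-2.04), the pentose phosphate enzyme Pgls (-2.02), the NF-kappaB inhibitor Nfkbib (-1.999) and Entr1 (-1.89).

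Genes with higher signal in Pac1-/- cells were dim, with mean intensities between 102 for Frmd4b and 190.5 for Pkig among the 12 named. In wild-type cells all of them but Pkig read below 100 on both arrays, so none of these differences has an exact size. Satb1 had log2 intensities of 7.70 ± 0.12 in Pac1-/- and 5.49 ± 0.27 in wild-type cells (SD, n = 2), a difference of 2.21 ± 0.37 (SE). Lyz1 differed by 2.18 ± 0.47, Eomes by 1.93 ± 0.40 and Cpe by 1.91 ± 0.40. The remaining genes were Smim27 (2.86), the palmitoyltransferase Zdhhc6 (2.56), Tmem87a (2.41), Med12l (2.10), Zfp53 (2.08), Frmd4b (2.01), the protease inhibitor Spink4 (1.97) and the protein kinase A inhibitor Pkig (1.91). Smim27 was next to the floor of 16 on both wild-type arrays and Zdhhc6 on wild-type replicate 2, so the size of their differences depends on that floor too. For Pkig and for Gsr, 1 of the 2 tested probe sets had the opposite sign.

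**Figure D1:**
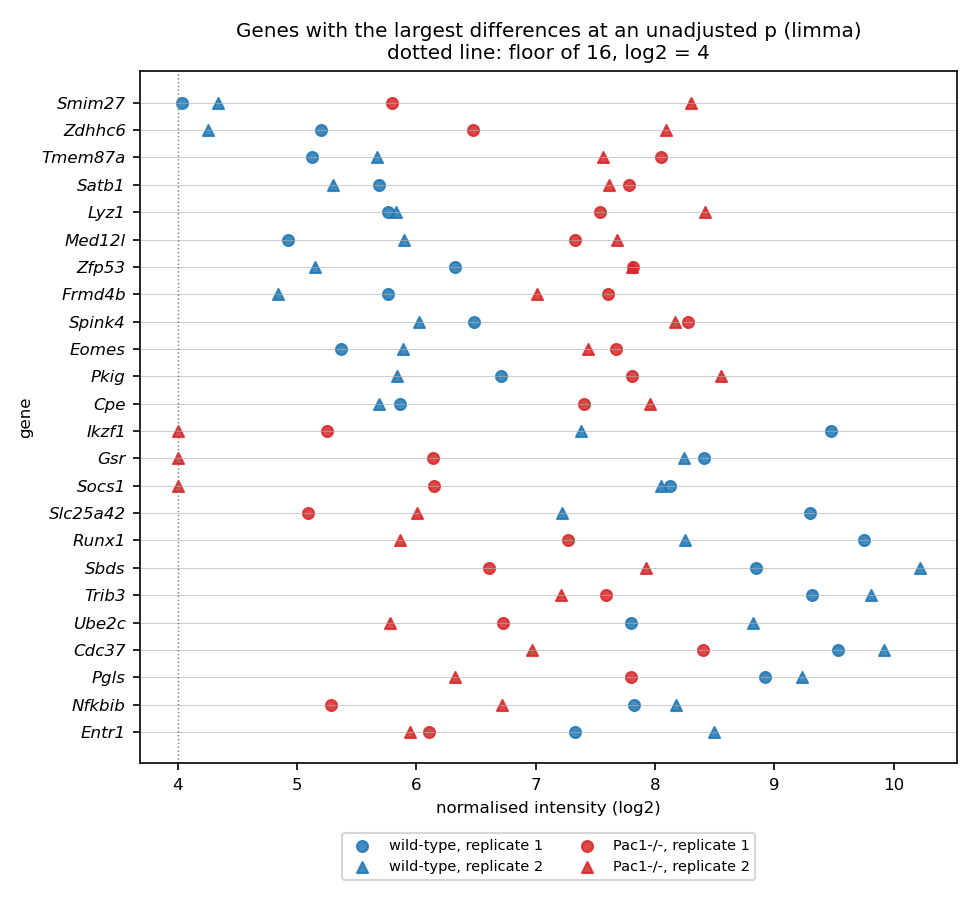
Normalised log2 intensity (x axis) of the 24 genes named by rule (y axis) on each array; blue marks are wild-type and red marks Pac1-/-, circles replicate 1 and triangles replicate 2. The genotypes do not overlap in any of these genes, which were picked for that; the Pac1-/- replicate 2 array lies at the floor of 16 for Ikzf1, Gsr and Socs1.

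By correlation and sum of squares, but not by every measure, arrays that shared a replicate number resembled each other more than arrays that shared a genotype. Across the tested probe sets, which are not independent replicates, log2 intensities correlated at r = 0.885 between the replicate 1 arrays and 0.750 between the replicate 2 arrays, against 0.437 between the wild-type arrays and 0.468 between the Pac1-/- arrays. Of the sum of squares over tested probe sets, 71.9% lay between the replicate numbers, 17.9% between the genotypes and 10.2% in the remainder. The median absolute log2 difference was 0.453 between the replicate 1 arrays but 0.688 between the replicate 2 arrays, against 0.558 between the wild-type and 0.625 between the Pac1-/- arrays, so the typical probe set differed most in the replicate 2 pair of these 4. The sex-linked genes followed the replicate number too. Eif2s3y, on the Y chromosome, read 219 and 275 on the replicate 1 arrays and 1.0 and 2.1 on the replicate 2 arrays, while the brightest probe set of Xist read 47.7 and 41.7 on the replicate 1 arrays and 2952 and 984 on the replicate 2 arrays, for wild-type and Pac1-/- in turn.

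**Figure D2:**
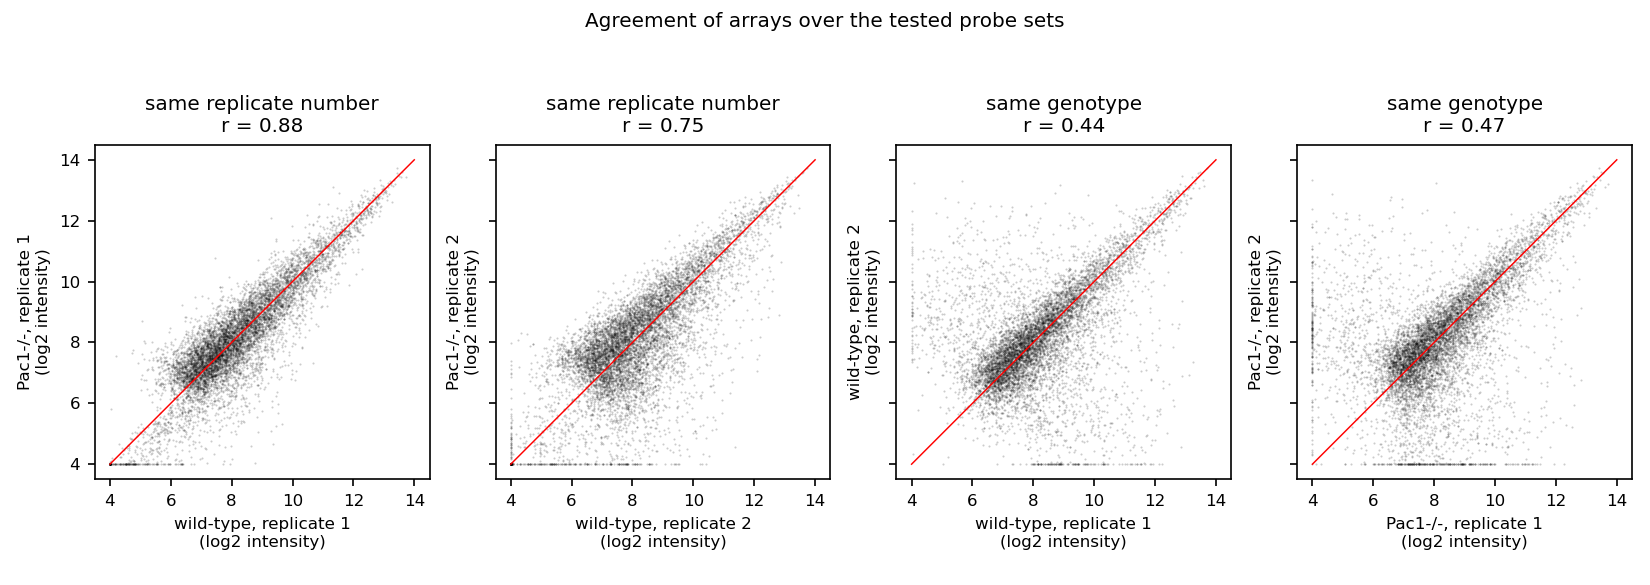
Log2 normalised intensity of every tested probe set on one array (x axis) against another (y axis), for the pairs that share a replicate number (left) and the pairs that share a genotype (right); the red line marks equal values. Correlations were 0.885 and 0.750 within replicate numbers, and 0.437 and 0.468 within genotypes, where many probe sets lie far from the line.

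Genes were next grouped by 23 lists fixed before the data were examined, of which 18 had at least 5 tested genes. In Pac1-/- cells the heat shock and unfolded protein response genes and the cell cycle genes fell relative to the other genes by limma's camera test with its preset correlation. With an estimated correlation neither list was called (adjusted p = 0.659 for both), nor by fry (adjusted p = 0.457 for both). The estimates were -0.017 for heat shock and -0.0441 for the cell cycle, below the preset 0.01. A higher correlation between members was therefore not what ended the camera calls. No other list was called, and 0 members of any list passed limma's adjusted p over all genes or adjusted over the list alone.

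In the heat shock and unfolded protein response list, 23 of 33 tested genes were lower and 10 higher in Pac1-/- cells, with a median log2 difference of -0.41 and a camera adjusted p of 0.0153 (0.659 with an estimated correlation). The median was -0.22 between the replicate 1 arrays and -0.63 between the replicate 2 arrays. Trib3 and the endoplasmic reticulum disulphide isomerase Pdia4 (-1.84 ± 0.52, SE) were past the unadjusted limma test, while Sesn2 (-2.59 ± 0.93) and the eIF2alpha phosphatase subunit Ppp1r15a (-1.47 ± 0.64) were not. The call ended on the values as deposited (camera adjusted p = 0.141), with median centring (0.131) and with no intensity minimum (0.177). It also ended without wild-type replicate 2 (median at 0.11) and without Pac1-/- replicate 1. With an array left out part of the replicate difference enters too, so such an ending need not come from the genotype difference. The Pac1-/- arrays also had more 3' signal relative to 5' signal for beta-actin within each replicate number, 293 against 109 for replicate 1 and 54.8 against 1.58 for replicate 2. Pac1-/- replicate 2 had a GAPDH ratio of 191 against 0.84 on wild-type replicate 2, but for replicate 1 these were 1.36 against 0.80. The beta-actin 3' to middle ratios of the replicate 1 arrays, 357 against 131, were above the 3' to 5' ones. Signal therefore did not fall steadily from 3' to 5' there.

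In the cell cycle and proliferation list, 18 of 22 tested genes were lower and 4 higher, with a median log2 difference of -0.31 and a camera adjusted p of 0.0153 (0.659 with an estimated correlation). The median was -0.40 between the replicate 1 arrays and -0.21 between the replicate 2 arrays. The ribonucleotide reductase subunit Rrm2 (-1.73 ± 0.51, SE) and Ube2c were past the unadjusted test, while the replication licensing factor Mcm3 (-1.23 ± 0.73) and the cyclin Ccnd3 (-1.01 ± 0.66) were not. The call ended with no intensity minimum (camera adjusted p = 0.714). It also ended without wild-type replicate 1 and without Pac1-/- replicate 1, where part of the replicate difference enters the genotype difference. Median centring moved the median of all tested probe sets to 0.69, and on that scale the list medians were 0.25 for heat shock and 0.18 for the cell cycle, above 0 but below the other genes.

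The mediators that mast cells release did not differ in one direction. Of 42 cytokine and chemokine genes on the list, 18 were bright enough to test, with 7 higher and 11 lower in Pac1-/- cells, a median log2 difference of -0.19 and a camera adjusted p of 0.65. The median was -0.81 between the replicate 1 arrays and 0.29 between the replicate 2 arrays. It was also above 0 without wild-type replicate 1 (0.05), wild-type replicate 2 (0.50) or Pac1-/- replicate 1 (0.61). Median centring put it at 0.51, but it put the median of all tested probe sets at 0.69, so the list stayed below the other genes there. The members with the lowest p were the chemokine Ccl6 (0.79 ± 0.42, SE), the EGF family member Hbegf (-1.56 ± 0.90), the interleukin gene Il1b (0.51 ± 0.38) and the growth factor Csf1 (-0.57 ± 0.48; 0.06 with median centring), and none passed at the unadjusted level. Il6, Ccl3 and Tnf, singled out as typical mast cell products after their values were seen, had log2 differences of -0.54 ± 2.11, -0.38 ± 1.47 and -0.02 ± 0.73. With median centring each was above 0 (0.24, 0.47 and 0.35) but below the median of all tested probe sets.

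Among immediate-early transcription factors, 8 of 21 tested genes were higher and 13 lower (median -0.09, camera adjusted p = 0.65). Zfp36l1 (1.30 ± 0.36, SE), a binder of AU-rich mRNA, was past the unadjusted test, while Klf6 (1.06 ± 0.42), Klf10 (1.25 ± 0.81) and Junb (-2.22 ± 0.88) were not. The feedback regulators of MAP kinase signalling, other phosphatases and Sprouty proteins among them, had 8 of 15 genes higher and 7 lower. Their median was 0.01 but their mean was -0.12 and camera's direction was down (adjusted p = 0.441), and their median was -0.46 between the replicate 1 arrays and 0.56 between the replicate 2 arrays. The median was -0.39 without wild-type replicate 2 and 0.36 without wild-type replicate 1. These fits set 1 wild-type array against both Pac1-/- arrays. The list's median replicate 2 minus 1 difference in wild-type cells, -0.7444, therefore enters them with opposite signs. On all 4 arrays camera's adjusted p was 0.827 with an estimated correlation. The lowest p belonged to the adaptors Dok2 (-1.03 ± 0.42) and Dok1 (-0.40 ± 0.41), the Ras GTPase-activating protein gene Rasa1 (0.79 ± 0.49) and the phosphatase Dusp14 (-1.06 ± 0.94).

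The genes of the signalling cascades themselves were split. Of the MAP kinase cascade components, 12 of 22 were higher and 10 lower (median 0.15, camera adjusted p = 0.755). The kinase gene Map3k3 (1.23 ± 0.35, SE) and the Ras exchange factor Sos2 (1.63 ± 0.47), both below 100 on both wild-type arrays, were past the unadjusted test. The ribosomal S6 kinase gene Rps6ka3 (1.05 ± 0.42) and Map2k3 (-1.04 ± 0.52), which encodes an activator of p38, were not. In the NF-kappaB list, 10 of 16 were higher (median 0.23, adjusted p = 0.866). The apoptosis inhibitors Birc3 (1.33 ± 0.38) and Birc2 (1.18 ± 0.40) and Nfkbib were past the unadjusted test, and the protease gene Plau (2.74 ± 1.18), at the floor on wild-type replicate 2, was not. In the calcium and NFAT list, 9 of 12 were higher (median 0.32, adjusted p = 0.712), with Nfatc3 at 0.81 ± 0.34, the calcineurin subunit Ppp3ca at 0.71 ± 0.36, Camk2g at 0.73 ± 0.43 and the calcium channel Orai1, next to the floor on Pac1-/- replicate 1, at -2.27 ± 1.28.

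In proximal FceRI signalling, 14 of 19 genes were lower (median -0.31, camera adjusted p = 0.139). The median was 0.03 between the replicate 1 arrays and -0.77 between the replicate 2 arrays, and the list was called lower when the probe sets of a gene were averaged (adjusted p = 0.037 with camera's preset correlation; 0.827 with an estimated one, on the brightest probe sets). Its members with the lowest p were the adaptor Lat (-0.61 ± 0.38, SE), the phosphatase Ptpn11 (0.58 ± 0.44) and the kinases Prkcb (0.47 ± 0.36) and Csk (-1.06 ± 0.94). With median centring Lat was at 0.18, below the median of all tested probe sets (0.69). In the mast cell granule, protease and receptor list, 9 of 20 genes were higher and 11 lower (median -0.07, adjusted p = 0.441), with the stem cell factor receptor Kit at 0.81 ± 0.44, Mitf at 0.68 ± 0.44 and the tryptase Tpsab1 at -0.69 ± 0.50. A second tryptase, Tpsb2 (-1.88 ± 1.44), read 476 on Pac1-/- replicate 2 and between 5838 and 7259 on the other arrays, and without that array its difference was 0.02.

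The survival and metabolic lists gave no call. Of the apoptosis and survival genes, 17 of 25 were higher (median 0.46, camera adjusted p = 0.441). Bcl2 (-1.79 ± 0.62, SE), Birc3 and Birc2 were past the unadjusted test, and Ccng1 (1.39 ± 0.55) was not. Glycolysis genes were higher in 13 of 17 (median 0.37, adjusted p = 0.441). Their median was 0.66 between the replicate 1 arrays and 0.03 between the replicate 2 arrays, with Pgk1 at 1.04 ± 0.51, P4ha1 at 1.24 ± 0.61, Aldoc at 1.73 ± 0.90 and Pfkl at -1.45 ± 0.79. Cholesterol synthesis genes were lower in 11 of 18 (median -0.28, adjusted p = 0.208), with Ebp at -1.21 ± 0.58, Nsdhl at -0.88 ± 0.54, Hsd17b7 at -0.69 ± 0.44 and Idi1 at 0.58 ± 0.38. Ribosomal protein genes were lower in 21 of 35 (median -0.07, adjusted p = 0.162), with Rps27 at -1.06 ± 0.50, Rpl8 at -0.89 ± 0.52, Rps14 at -1.12 ± 0.81 and Rps19 at -0.86 ± 0.59. Interferon response genes were lower in 5 of 8 (median -0.07, adjusted p = 0.502), with Tap1 at 1.02 ± 0.48, Psmb8 at -2.20 ± 1.16, Ifi35 at -1.67 ± 0.92 and Ifitm3 at 0.47 ± 0.45. Prostaglandin and leukotriene genes were higher in 4 of 6 (adjusted p = 0.848), with a median of 0.19 but a mean of -0.01. Of these, Pla2g4a was at 0.63 ± 0.52, Alox5ap at 0.18 ± 0.35, and the prostaglandin receptors Ptger3 and Ptger4 at 0.26 ± 0.49 and 0.20 ± 0.44.

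Markers of other cell types were few. Of 187 probe sets of such markers, between 4 and 8 per array had an intensity of at least 500. No gene of the neutrophil list was bright enough to test. Of the macrophage list 5 of 6 genes were lower (median -0.19, camera adjusted p = 0.871). Lyz1, the other member, had the lowest p adjusted over the list alone of any list (0.0703, limma), and Apoe (-1.85 ± 1.85, SE) was at the floor on Pac1-/- replicate 2. Adgre1 differed by -0.18 ± 0.34 and Lgals3 by -0.44 ± 2.10, and by 0.41 and 0.40 with median centring. That scale put the median of all tested probe sets at 0.69, above these and the other centred values given in this paragraph. Erythroid and megakaryocyte markers were lower in 5 of 7 (median -0.11, adjusted p = 0.65), with Itga2b at -1.57 ± 0.85, Vwf at 0.55 ± 0.62, Gp5 at -0.35 ± 0.50 (0.09 with median centring) and Tal1, which mast cells also express, at 0.58 ± 0.36. The lists with fewer than 5 tested genes are given by values only. The basophil and eosinophil genes were Il18rap (-0.88 ± 0.95), Ccr1 (-0.35 ± 2.02) and Gzmb (-0.13 ± 0.38), a granzyme that is on the mast cell list too, with Ccr1 at 0.07 and Gzmb at 0.59 with median centring. The lymphocyte gene was Zap70 (-0.79 ± 0.83). The stromal, endothelial and adipocyte genes were Pecam1 (-1.99 ± 1.14), Vcam1 (-1.91 ± 1.86), Sparc (-0.44 ± 2.62) and Acta2 (0.10 ± 2.64, but -0.32 on the values as deposited), and the sex-linked genes were Xist (-0.89 ± 2.78), Uty (-0.75 ± 2.17) and Eif2s3y (0.16 ± 2.08). Vcam1, Sparc, Uty and Eif2s3y were at the floor on both replicate 2 arrays, so that pair had a difference of 0 by construction and the values given for them have no exact size.

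**Figure D3:**
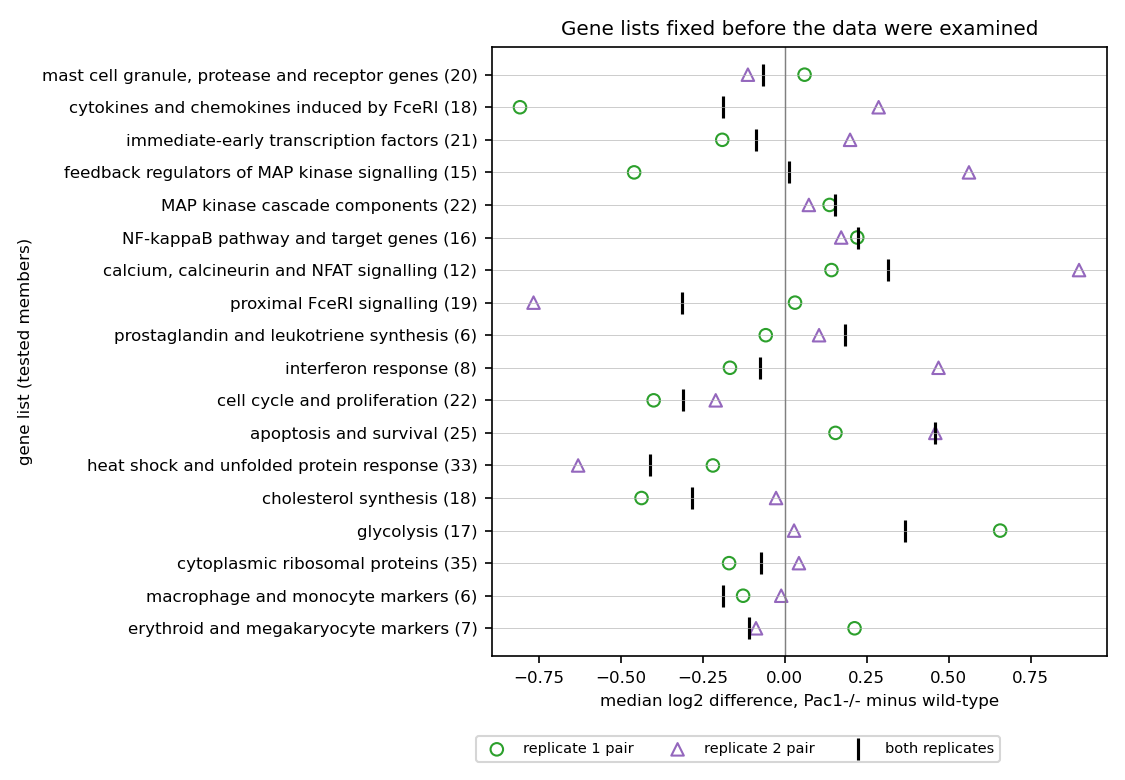
Median log2 difference, Pac1-/- minus wild-type (x axis), of each fixed gene list with at least 5 tested members (y axis, number tested in brackets), between the replicate 1 arrays (circles), between the replicate 2 arrays (triangles) and over both (bars). The heat shock list (-0.22 and -0.63) and the cell cycle list (-0.40 and -0.21) lie below 0 in both pairs, while the cytokine list lies on opposite sides (-0.81 and 0.29).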

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

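All tests in this part except the comparison of probe sets of a gene, the other probe sets of list members and the random lists were chosen after the results were seen. These exceptions were written before their own results were seen, but the lists examined had been picked by the camera result. Signals outside the tested probe sets stood out in 3 cases. The hybridisation controls, bacterial and phage transcripts added to each sample, were 1.711-fold brighter on the Pac1-/- arrays on average. The GAPDH 3' to 5' signal ratio on Pac1-/- replicate 2 was 190.831, against 0.80 to 1.36 on the other arrays. The beta-actin 3' to 5' ratio on Pac1-/- replicate 1 was 292.828, against 108.6 on wild-type replicate 1, 1.58 on wild-type replicate 2 and 54.8 on Pac1-/- replicate 2.

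The brighter hybridisation controls may come from a larger scaling factor on the Pac1-/- arrays, as less cRNA of the sample would need. Of 12 bright controls, 12 were higher in Pac1-/- in both pairs, with a mean of 1.65-fold (SD 0.21 on the log2 scale) for replicate 1 and 1.77-fold (SD 0.29) for replicate 2. A larger amount of controls added to the Pac1-/- samples would give the same pattern and was not tested. No biological explanation was tested.

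The heat shock and cell cycle lists were lower in Pac1-/- cells by camera with its preset correlation, but neither was called with an estimated one (adjusted p = 0.659 for both). The estimates, -0.017 and -0.0441, were below the preset 0.01. If loss of 5' signal on Pac1-/- replicate 2 alone had caused this, the replicate 1 pair would show nothing. There the means of the lists less that of all tested genes were -0.3584 (SE 0.1346 over genes) and -0.6287 (SE 0.1482), so both lists were lower in that pair too. The lists were picked for a low mean that includes this pair, and the SE is over genes on 1 array per genotype. These values therefore cannot decide whether Pac1-/- replicate 2 was the whole cause. Among 10000 random lists matched on mean intensity, the heat shock mean was at percentile 0.01, the smallest they can give, and the cell cycle mean at 0.15. The random lists had median means of 0.0447 and 0.0044, against -0.5416 and -0.4792 for the lists, which argues against a difference that depends on intensity alone. Random lists ignore correlation between genes and resemble the camera test that picked these lists. The percentiles are therefore not separate support for the calls. The other tested probe sets of 18 heat shock genes had a mean difference of -0.4698 (SE 0.2049) less that of all tested probe sets, so that list was lower by these probe sets too. Those of 10 cell cycle genes had -0.3685 (SE 0.3403), so for that list differences of single probe sets cannot be told apart from differences of genes. Both SEs are over genes on the same 4 arrays and do not measure the spread between cultures. An effect of Pac1 remains a hypothesis for both lists, beside 3' bias. The beta-actin 3' to 5' ratio was higher in Pac1-/- in both pairs. On the replicate 1 arrays, however, beta-actin signal did not fall steadily from 3' to 5', and the GAPDH ratios were 1.36 in Pac1-/- against 0.80 in wild-type.

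The replicate numbers held more of the sum of squares than the genotypes (71.9% against 17.87%), though the typical probe set differed more between the replicate 2 arrays (median absolute log2 difference 0.6884) than between arrays of a genotype (0.5579 and 0.6248), and much of the replicate difference may lie in single probe sets rather than in genes. Over 1468 genes with at least 2 tested probe sets, the replicate difference of the brightest correlated with that of the next at r = 0.1373 (95% interval 0.0735 to 0.1988), where differences between transcripts would carry over; the genotype difference correlated no better (r = 0.1014, same sign in 50.8%). Sex-linked genes held 0.2765% of the replicate sum of squares, but so few probe sets cannot hold much of it whatever their differences, so this share tests nothing. By their brightest probe sets, the Y-linked Eif2s3y and Uty were above the floor only on the replicate 1 arrays, and Xist was higher on the replicate 2 arrays. Male mice for replicate 1 and female mice for replicate 2 would give this, but the labels used here give no sex. How much of the replicate difference the sex of the mice accounts for stays open. Loss of abundant transcripts on the replicate 1 arrays cannot be told apart from chance: 2 ribosomal protein probe sets were under 100 on both replicate 1 arrays and at least 500 on both replicate 2 arrays, against 0 the other way round, which is too few. The arrays' production batch and preparation day are not given in the sources used here.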

How the results depend on the processing

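No probe set had an adjusted p under 0.05 in limma under any of the 12 alternatives to which the fit applied. The simulation recovered few changes at the measured spread, but it gave every probe set 1 pooled spread. It therefore does not show how many changes would be recovered among probe sets that vary less. The lowest adjusted p over these alternatives was 0.191, with no intensity minimum. At an unadjusted p under 0.05 there were 1762 probe sets with no minimum, 110 with a minimum of 200, 666 with the minimum applied after the adjustment, and from 79 to 408 with an array left out, against 263. With the replicate number as a block there were 899, where chance would give 388.5, with 328 higher and 571 lower in Pac1-/- cells (36.5% higher, against 66.5%), and 247 of the 263 were kept. In this paired fit the same 2 lists were called, and the deviations of same-numbered arrays from their genotype means correlated at 0.751, but nothing in the labels says that a number marks a shared day or animal. Of the lists, 0 were called with an estimated correlation, 0 by fry, 0 with no intensity minimum, 1 on the values as deposited, 1 with median centring and between 0 and 2 with an array left out. The Dusp2 difference lay between -0.88 and 0.003 with an array left out, and the cytokine list median between -0.0751 and 0.6117, the latter also at 0.5117 with median centring. Median centring turned Csf1 to 0.0581, Lgals3 to 0.4027, Gzmb to 0.5879, Ccr1 to 0.0706, Gp5 to 0.0850, Ccl3 to 0.4672, Il6 to 0.2359, Tnf to 0.3509, Lat to 0.1829 and Adgre1 to 0.4109. It also moved the median of all tested probe sets to 0.691, above each of these, so relative to the other genes none of them turned. This setting takes the place of the quantile normalisation. Away from the floor it adds the same amount to the difference of every gene on the values as deposited. Acta2 was at -0.3162 on the values as deposited and at -0.5731 with a floor of 64. With an array left out, the differences ranged from -0.9017 to 0.8524 for Tnf, -4.3411 to 0.5309 for Vcam1, -1.9612 to 1.2005 for Ccl3, -2.9449 to 1.8688 for Il6, -1.859 to 0.1083 for Il18rap, -3.7742 to 0.0172 for Tpsb2, -4.327 to 0.6234 for Apoe, -1.6938 to 0.1157 for Zap70, -2.9682 to 3.164 for Acta2, -2.2869 to 1.5782 for Ccr1, -2.1459 to 0.0324 for Csk, -2.2032 to 0.0905 for Dusp14, -1.8877 to 2.2145 for Eif2s3y, -0.8476 to 0.1433 for Gp5, -0.348 to 0.0805 for Gzmb, -2.6278 to 1.7447 for Lgals3, -0.1713 to 0.6933 for Ptger3, -0.1152 to 0.507 for Ptger4, -3.154 to 2.265 for Sparc, -3.1529 to 1.657 for Uty, -0.147 to 1.2456 for Vwf and -3.8656 to 2.0861 for Xist. Each of these fits sets 1 array of a genotype against both replicate numbers of the other, so part of the replicate difference enters by design. The ranges therefore do not measure how stable the genotype difference alone was. In the other 1204 of 1248 comparisons of a named gene under an alternative, the direction was that reported and no gene passed the adjusted test. Many of these could not turn, because the intensity minimum, its order, the eBayes trend and the replicate block leave a difference unchanged. Genes picked for groups that do not overlap also keep their direction with any array left out. The count is therefore no measure of how stable the directions are. Signal near the background limits the dim genes, since 14856 probe sets were below the intensity minimum.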

Other observations

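Single probe sets of mediators that activated mast cells secrete differed between the replicate numbers, some higher and some lower in replicate 2. Between the 2 brightest probe sets of a gene the replicate difference correlated at only r = 0.1373, so these need not be differences of the transcripts. The fixed cytokine and chemokine list did not shift one way, with a median replicate 2 minus 1 difference of 0.1766 in wild-type and -0.1924 in Pac1-/- cells. The genes named here were picked after their values were seen, from a limma fit with genotype and replicate number as terms, in which 1126 of 7770 probe sets passed an adjusted p under 0.05, 549 higher and 577 lower in replicate 2. On the log2 scale, replicate 2 was higher by 3.34 ± 0.49 (SE) for Ccl2 and 2.72 ± 0.49 for Ccl3, with limma adjusted p of 0.0028 and 0.00748. Il6 (adjusted p = 0.00274), Il4 (0.042), Ccl4 (0.00118) and Ccl7 (0.00755) were higher too and the chemokine Ccl12 (0.00413) lower, by sizes left out because each read below 100 on at least 1 array. Lower in replicate 2 were the early response genes Myc (-3.49 ± 0.54, adjusted p = 0.00362) and Ier2 (-3.60 ± 0.72, adjusted p = 0.0126). Also lower were the growth factors Il3 (adjusted p = 0.00115) and Csf2 (0.0455) and the early response gene Nr4a2 (0.000876), whose differences have no exact size because both replicate 2 arrays, or for Csf2 the wild-type one alone, were at or next to the floor of 16. For wild-type and Pac1-/- in turn, Il3 read 556.0 and 213.9 on replicate 1 and 8.1 and 6.2 on replicate 2, Csf2 1020.1 and 641.2, then 6.5 and 250.3, and Nr4a2 484.3 and 291.4, then 12.2 and 18.4. Tnf (limma adjusted p = 0.53), below 100 on wild-type replicate 2 and so given without a size, and Egr1 (0.38 ± 0.50, adjusted p = 0.819) were not called.

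For several genes, 2 probe sets gave opposite differences between the replicate numbers. Egr2 was lower in replicate 2 by one probe set (limma adjusted p = 0.0343) and higher by another (0.0023), and Cebpb was higher by one (0.00303) and lower by another (0.0171), again with arrays below 100 and no sizes given. For the ribosomal protein gene Rps18, a probe set read 9.6 and 9.7 on the replicate 1 arrays and 5128 and 2294 on the replicate 2 arrays, while another read between 5711 and 7110 on all 4. The amino acid response genes Asns and Atf4 had brightest probe sets higher in replicate 2 (adjusted p = 0.00036 and 0.000623), but a further Atf4 probe set was not called (adjusted p = 0.832). Each mediator named above for replicate 2 rests on 1 tested probe set.

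A knockout made in cells of one mouse strain and bred to another can carry variants of the first strain around the targeted gene, which may change expression or probe binding there. This was tested on the tested genes among the 50 protein-coding genes on either side of Dusp2, a test planned before its result was seen. Of 29 such genes 1, Eid1, was past the unadjusted limma test (log2 difference 1.37), against 145 of 4969 other genes (one-sided Fisher's exact test p = 0.578). With so few genes past the test the explanation stays open, and the strains of the mice are not given in the sources used here.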
